A study of Mus musculus with 36 samples.

How the data were processed

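The deposited table held 1 intensity value per probe set and array on a linear scale; how the authors summarised and normalized the intensities is not given in the sources used here. The cells were mouse embryonic fibroblasts, wild type or PKBa-/-, and per the labels biotinylated cRNA was hybridized to Affymetrix arrays. Values ran from 8.62 to 19337 over 22690 probe sets, and the highest array median was 1.09 times the lowest. The total signal of an array is no depth; the number of arrays limits the precision.

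Of the probe sets, 20380 had 1 gene, 691 several, 1555 none and 64 were controls; probe sets with 1 gene were used. Each of 12393 genes was read on its brightest probe set. Values were taken as log2(signal + 32) without further normalization, since the medians lay within 1.2-fold. The 40% of genes with the lowest mean of these log2 values were not tested, which left 7436 genes with a mean log2 that corresponds to a signal of about 123 or more. Limma 3.58.1 in R 4.3.3 fitted 10 group means (genotype by time) to the 36 arrays with empirical Bayes moderation, with 26 residual and 5.40 prior degrees of freedom. Its moderated test was used for each contrast, two-sided, with p adjusted by Benjamini and Hochberg within each contrast and a threshold of 0.05; a gene that met it is said to have passed.

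Contrasts were PKBa-/- minus wild type averaged over the 5 times and at each time, each later time minus time 0 within each genotype, and the difference between genotypes of those changes, also as an F test over the 4 later times. Of 38 gene lists, 32 had at least 5 tested genes and were tested by camera with a preset correlation of 0.01, adjusted over lists within each contrast. Camera with an estimated correlation and fry were run beside it. The comparisons, filter, offset, lists and the alternatives called planned were fixed before the data were examined.

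Named genes followed a rule, given here for the genes reported: Akt1, Akt2 and sex-linked genes; the 12 highest and 12 lowest genotype differences averaged over times with the same sign at the 5 times; for each genotype the 6 highest and 6 lowest changes at time 48 and the 4 highest and 4 lowest at times 2, 6 and 24; the 12 smallest interaction p-values; and up to 4 members of each list called over time or averaged over times. The report gives a part of these and marks those outside the rule.

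Arrays with the same replicate pair, 1 and 2 or 3 and 4, of a group correlated at 0.993 on average and at 0.969 with the other pair, and limma estimated a correlation of 0.66 within pairs. It was checked whether replicate numbers pair arrays across groups: residual correlations ran from 0.0329 to 0.705 between time 0 and times 6, 24 and 48 within a genotype, from -0.0126 to 0.151 and from -0.007 to 0.076 between times 0 and 2 in PKBa-/- and wild type, and from -0.116 to 0.324 between genotypes, so a fit with the replicate number is given beside the main one.

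The procedure was tested on simulated data of 7436 genes. With independent arrays it recovered 77.6%, 95.5% and 100% of 1.5-, 2- and 4-fold changes with 6 false calls. Where the arrays of a pair shared a deviation, 353 calls were false with arrays as replicates, and 11 with pair averages, which recovered 44.8%, 83.6% and 100%. Alternatives tried were other offsets and filters, the mean of all probe sets, quantile normalization, an intensity trend, array weights, blocks for replicate number or replicate set, each set alone, the compared groups alone, leaving out each array, and, added after the data were seen, pair averages, a random pair effect and a block for replicate set within genotype. Probe sets with several or no genes were left out of the comparisons.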

Results

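RNA from mouse embryonic fibroblasts of 2 genotypes, wild type and PKBa-/- (lacking Akt1, which encodes the protein kinase PKB alpha), was measured on 36 Affymetrix arrays. The labels give the times 0, 2, 6, 24 and 48 without a unit. Each genotype had 4 arrays at times 0, 6, 24 and 48 and 2 arrays, replicates 1 and 2, at time 2. The median signal per array ran from 134 to 145, and the number of arrays limits the precision. Values below are log2 differences ± SE from the limma fit with adjusted p, or mean signals ± SD. The 2 arrays of replicates 1 and 2, or of replicates 3 and 4, of a group correlated at 0.982 to 0.997 and stood closer to each other than to the other pair. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between arrays alone. The series title speaks of DMEM-treated cells, while the extraction protocol also describes an adipocyte induction medium; the sample labels do not say which the arrays received.

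The first comparison asked how far the targeted gene and its relatives differed between the genotypes. Akt1 signal was 1117 ± 183 (SD, n = 18) in wild type and 74.3 ± 14.3 (SD, n = 18) in PKBa-/- arrays on its brightest probe set. That was a difference of -3.45 ± 0.07 (adjusted p = 5.9e-29), and the highest PKBa-/- array (103) lay far below the lowest wild type array (843). Another Akt1 probe set gave 747 ± 155 against 47.9 ± 9.67. Akt2, which encodes the related kinase PKB beta, differed by -0.02 ± 0.04 (adjusted p = 0.73). Xist, the RNA of the inactive X chromosome, was read in both genotypes, at 5261 ± 482 and 3186 ± 419.8 (n = 18 each), and was lower in PKBa-/- (log2 difference -0.71 ± 0.04, adjusted p = 3.0e-15). The Y-linked gene Eif2s3y stayed near the lowest signals, with means of 11.5 ± 0.594 and 11.5 ± 0.723.

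**Figure D1:**
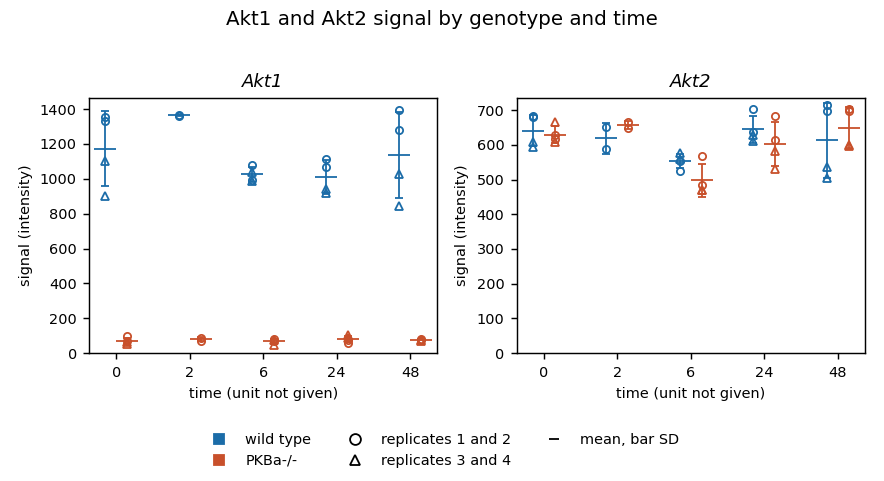
Signal of Akt1 and Akt2 (brightest probe set of each, linear scale) on each array, by time on the horizontal axis (unit not stated) and genotype by colour; horizontal marks are group means with SD. No PKBa-/- array exceeded 103 for Akt1, while the wild type arrays ran from 843 to 1395.

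Averaged over the 5 times (18 arrays of each genotype), the genes with the largest differences included genes of tissue identity and matrix. Higher in PKBa-/- were Tnmd, a tendon membrane protein (5.24 ± 0.08), the homeobox gene Hoxc8 (4.57 ± 0.08), the matrix protein gene Dpt (4.22 ± 0.05) and the zinc-finger factor Zic1 (4.00 ± 0.07). The growth factor Ptn (3.59 ± 0.20), the amino acid transporter Slc38a4 (3.07 ± 0.05) and the collagen genes Col6a3 (2.92 ± 0.21) and Col7a1 (2.68 ± 0.07) were also higher. Lower in PKBa-/- were Upk3b, a uroplakin gene of urothelium and mesothelium (-5.61 ± 0.06), the crosslinking enzyme Tgm2 (-5.48 ± 0.08), prostacyclin synthase Ptgis (-4.45 ± 0.06) and the transcription factor Gata6 (-4.35 ± 0.11). The sialomucin Podxl (-4.26 ± 0.05), the retinaldehyde dehydrogenase Aldh1a1 (-4.13 ± 0.06), Gpm6a (-4.13 ± 0.05), the caveolar protein gene Cavin2 (-4.43 ± 0.09) and the Wnt agonist Rspo1 (-4.06 ± 0.06) were lower as well. 4845 of 7436 genes passed, 2718 higher and 2127 lower in PKBa-/-, and 153 were at least 2-fold higher and 249 at least 2-fold lower. With the 2 arrays of each pair averaged first, 3521 genes passed; 5428 passed within replicates 1 and 2 and 5259 within replicates 3 and 4, and 5171 with the replicate number as a covariate. Of the genes that passed, 4626 (95.5%) had the same sign in both replicate sets. That share is partly built in, since the fit that chose these genes held both sets.

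Genes of positional identity differed in both directions. In the list of Hox and positional genes, 12 of 24 tested genes were higher and 10 lower in PKBa-/- (12 and 10 adjusted over the list alone). With pair averages 17 of the 24 passed. Another 27 genes of this list lay below the signal limit and were not tested, although their highest group mean was 293. Hoxc6 (2.14 ± 0.05) and Hoxc9 (1.16 ± 0.07) were higher beside Hoxc8, whereas the more anterior genes Hoxa5 (-3.41 ± 0.04), Hoxa3 (-1.85 ± 0.06), Hoxb2 (-1.93 ± 0.06) and Hoxb3 (-1.40 ± 0.06) were lower. Among imprinted genes 9 of 15 were higher and 5 lower (9 and 5 adjusted over the list alone). They included the insulin receptor adaptor Grb10 (-3.27 ± 0.30), Nnat (-3.26 ± 0.13), the growth factor Igf2 (-2.09 ± 0.23) and Mest (2.37 ± 0.34). Plagl1, Rian, Sgce and Dlk1, which had passed, did not pass with pair averages. The size differed between replicate sets: Grb10 gave -4.16 within replicates 1 and 2 and -1.94 within replicates 3 and 4, Nnat -3.70 and -2.57, Igf2 -1.43 and -3.09, and Mest 1.39 and 3.91. Camera (limma) called neither list (adjusted p = 0.74 and 0.55), since their members went both ways. The Hox and imprinted genes named here, other than Hoxc8 and Slc38a4, were chosen after their values were seen.

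Cell cycle inhibitors and p53 targets, which restrain division after stress, were lower in PKBa-/- in 13 of 17 tested genes (13 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.42 with an estimated correlation), and 3 were higher. The lower genes included Trp53inp1 (-1.32 ± 0.10), Btg2 (-1.19 ± 0.05), Sesn1 (-0.84 ± 0.06) and Ccng1 (-0.63 ± 0.09). Targets of NRF2, the regulator of glutathione and detoxification enzymes, were lower in 8 of 13 tested genes (8 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.72 with an estimated correlation). They included the glutathione transferases Gsta4 (-2.09 ± 0.08) and Gstm2 (-1.46 ± 0.05) and the glutathione synthesis gene Gclm (-1.09 ± 0.06). Another 4 NRF2 targets were higher.

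**Figure D2:**
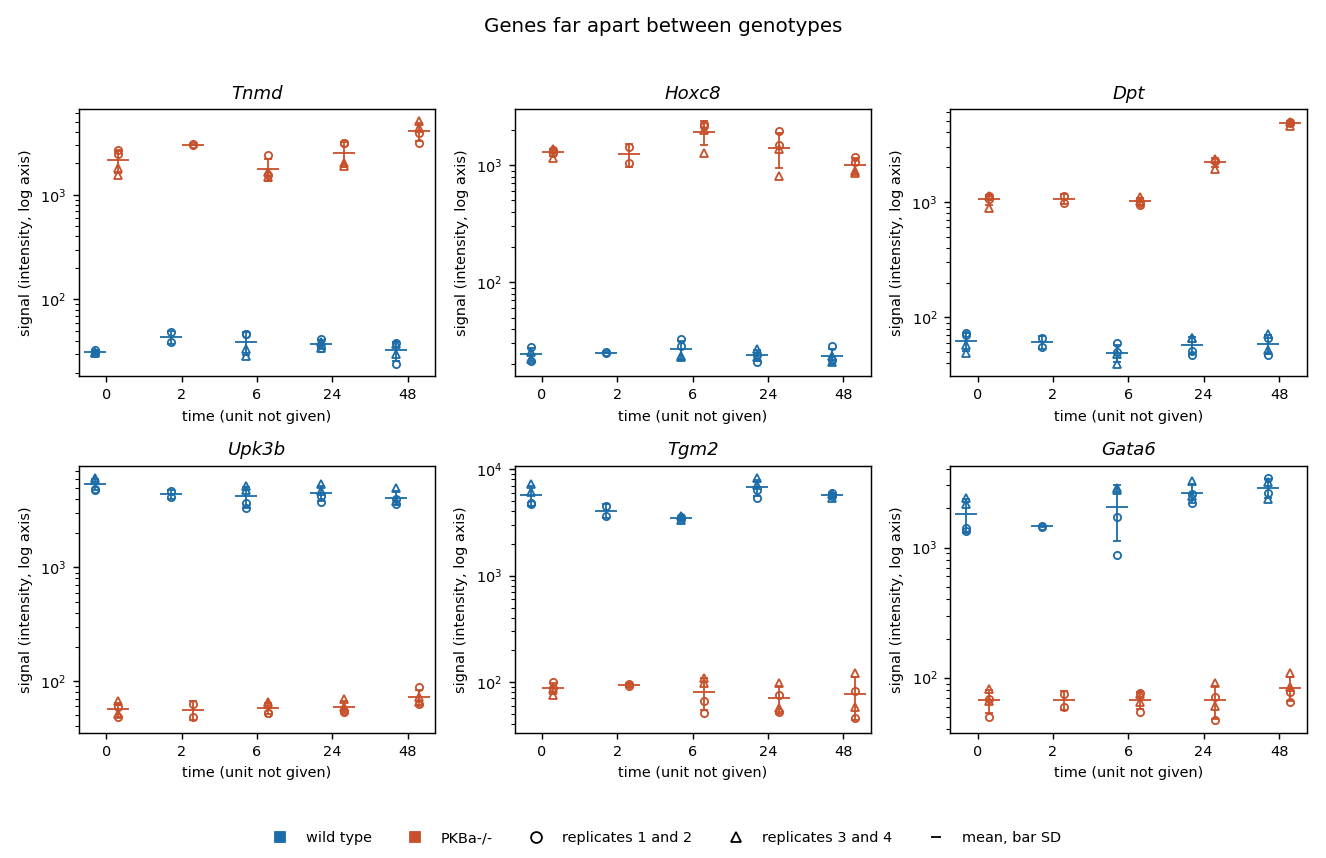
Signal on a log axis of 3 genes higher (Tnmd, Hoxc8, Dpt) and 3 genes lower (Upk3b, Tgm2, Gata6) in PKBa-/-, for each array by time and genotype, with group means and SD. At time 0, Tnmd read 31.5 ± 1.17 in wild type and 2129 ± 529 in PKBa-/-, and Upk3b 5395 ± 630.3 and 56.6 ± 8.16 (n = 4 each).

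The genotypes were then compared at each time, with 4 arrays against 4 except 2 against 2 at time 2. At time 0, genes of DNA replication were lower in PKBa-/- in 16 of 26 tested genes (16 adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.63 with an estimated correlation). TGF-beta targets were lower in 12 of 20 tested genes (12 adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.44 with an estimated correlation). 3072 of 7436 genes passed at time 0, 1551 higher and 1521 lower. The balance moved with the setting: pair averages gave 482 higher and 620 lower, and after quantile normalization 58.2% were higher. At time 2, 1748 of 7436 genes passed, and 3664 in a fit of replicates 1 and 2 alone. Without wild type time 2 replicate 1, PKBa-/- time 2 replicate 1 or PKBa-/- time 2 replicate 2 the count was 1016, 1112 and 1031, the single array left being assumed to vary like the other groups. At time 6, mitosis genes were lower in PKBa-/- in 18 of 26 tested genes (18 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.83 with an estimated correlation). Ribosome biogenesis genes were higher in 16 of 26 tested genes (16 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.67 with an estimated correlation). 2937 of 7436 genes passed at time 6. At time 24, cholesterol synthesis genes were higher in PKBa-/- in 13 of 19 tested genes (13 adjusted over the list alone, camera adjusted p = 4.9e-06, adjusted p = 0.62 with an estimated correlation), and 3169 of 7436 genes passed. Mitosis genes were higher at time 24 in 12 of 26 tested genes (15 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.75 with an estimated correlation). That difference was held by replicates 1 and 2, with a median of 0.74, and not by replicates 3 and 4, with -0.07.

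At time 48, mitosis genes were higher in PKBa-/- in 22 of 26 tested genes (24 adjusted over the list alone, camera adjusted p = 4.8e-05, adjusted p = 0.55 with an estimated correlation), with a median difference of 0.57. DNA replication genes were higher in 12 of 26 tested genes (12 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.58 with an estimated correlation). Ribosome biogenesis genes were higher in 20 of 26 tested genes (20 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.47 with an estimated correlation), and cholesterol synthesis genes in 13 of 19 tested genes (15 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.58 with an estimated correlation). TGF-beta targets were lower in 10 of 20 tested genes (11 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.25 with an estimated correlation). NRF2 targets were lower in 7 of 13 tested genes (7 adjusted over the list alone, camera adjusted p = 0.004, adjusted p = 0.25 with an estimated correlation). 3487 of 7436 genes passed at time 48, 1978 higher and 1509 lower. Averaging pairs first left 1102, 430, 1229, 1520 and 1726 genes at times 0, 2, 6, 24 and 48. The counts within replicates 1 and 2 were 3485, 3664, 3914, 4272 and 4198, and within replicates 3 and 4, which lack time 2, 3624, 3235, 3666 and 3512.

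The next comparisons followed each genotype from its own time 0. By time 2 in wild type (2 arrays against 4), the signalling inhibitor Rgs2 (4.32 ± 0.34), the receptor partner Ramp3 (3.66 ± 0.35), and the orphan nuclear receptors Nr4a1 (3.60 ± 0.20) and Nr4a2 (3.47 ± 0.16) rose. The aryl hydrocarbon receptor Ahr (-2.38 ± 0.22), the growth factor Bmp4 (-2.17 ± 0.27) and the insulin receptor substrate Irs1 (-1.68 ± 0.43) fell. In PKBa-/- the feedback inhibitor Errfi1 (3.75 ± 0.20), the chemokine Cxcl1 (3.72 ± 0.42), the phosphatase Dusp1 (3.50 ± 0.16) and the transcription factor Fos (3.34 ± 0.11) rose. In the same cells the thioredoxin-binding gene Txnip (-2.07 ± 0.12), Ccng2 (-1.76 ± 0.17) and Irs1 (-1.74 ± 0.43) fell. Immediate early genes, the first transcribed after a stimulus, rose in 15 of 28 tested genes (15 adjusted over the list alone, camera adjusted p = 3.9e-18, adjusted p = 2.0e-07 with an estimated correlation) in wild type. In PKBa-/-, 21 of 28 tested genes (22 adjusted over the list alone, camera adjusted p = 2.2e-37, adjusted p = 9.6e-11 with an estimated correlation) did. The median changes were 0.76 and 1.58. Camera, run on the gene-by-gene differences between these changes, called the list (adjusted p = 5.4e-05, and adjusted p = 0.008 with an estimated correlation). The median of those differences was 0.31. Within replicates 1 and 2 it was 0.25, with 12 of 28 genes up and 2 down (camera adjusted p = 5.7e-08, and adjusted p = 0.0018 with an estimated correlation).

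Mitosis genes fell by time 2 in 10 of 26 tested genes (17 adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.59 with an estimated correlation) in wild type. In PKBa-/-, 15 of 26 tested genes (19 adjusted over the list alone, camera adjusted p = 3.7e-10, adjusted p = 0.22 with an estimated correlation) did. In PKBa-/-, TGF-beta targets also rose by time 2 in 11 of 20 tested genes (11 adjusted over the list alone, camera adjusted p = 3.7e-10, adjusted p = 0.019 with an estimated correlation), with the inhibitor of differentiation Id1 (2.70 ± 0.12) and the activin-binding Fst (1.79 ± 0.26). Cytokine genes controlled by NF-kB rose in 6 of 14 tested genes (6 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.037 with an estimated correlation), with Ptgs2 (3.08 ± 0.26) and Ccl2 (2.31 ± 0.29) beside Cxcl1. Within replicates 1 and 2, the median change of the mitosis list was -0.23 in wild type and -0.38 in PKBa-/- (adjusted p = 0.29 and 0.08 with an estimated correlation). In PKBa-/- that of TGF-beta targets was 0.67 and that of NF-kB and cytokine genes 0.07 (adjusted p = 0.01 and 0.01 with an estimated correlation). The metallothionein Mt2 (3.00 ± 0.18 and 2.79 ± 0.18) and the glutathione synthesis gene Gclc (2.57 ± 0.15 and 2.10 ± 0.15) rose in wild type and PKBa-/-. In wild type 1332 of 7436 genes passed, 341 up and 991 down, and in PKBa-/- 1140, 476 up and 664 down. Time 2 exists in replicates 1 and 2 alone, and a fit of those arrays gave 2416 and 2003 genes, with the immediate early list up in both (adjusted p = 3.1e-04 and 2.3e-06 with an estimated correlation). Within those arrays Rgs2 changed by 4.04 in wild type, Errfi1 by 3.90 in PKBa-/-, and Irs1 by -2.17 and -1.93, although Irs1 did not pass with pair averages (adjusted p = 0.27 and 0.27). Pair averages left 203 in wild type, 97 up and 106 down, and 252 in PKBa-/-, where the balance turned, with 160 up and 92 down. Without wild type time 2 replicate 1 or 2, 629 and 834 genes passed in wild type, and without PKBa-/- time 2 replicate 1 or 2, 599 and 565 in PKBa-/-.

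By time 6 (4 arrays against 4), Ramp3 (3.77 ± 0.29), Rgs2 (3.20 ± 0.28) and Mt2 (3.02 ± 0.15) had risen in wild type. The chemokine Ccl2 (-2.82 ± 0.24), the growth factor receptor Pdgfrb (-2.77 ± 0.19) and the myosin kinase Mylk (-1.84 ± 0.23) had fallen. In PKBa-/-, the lubricating proteoglycan Prg4 (3.75 ± 0.58), the vitamin D receptor Vdr (3.49 ± 0.16), Mt2 (3.11 ± 0.15) and the hyaluronan synthase Has2 (2.25 ± 0.26) rose. The iron exporter Slc40a1 (-2.75 ± 0.13) and the matrix protease Adamts5 (-2.62 ± 0.11) fell. Ribosome biogenesis genes rose in 24 of 26 tested genes (24 adjusted over the list alone, camera adjusted p = 2.5e-16, adjusted p = 0.032 with an estimated correlation) in PKBa-/-, with Nolc1 (1.60 ± 0.10) and Rrp12 (1.16 ± 0.11). In wild type they rose in 15 of 26 tested genes (18 adjusted over the list alone, camera adjusted p = 2.0e-05, adjusted p = 0.37 with an estimated correlation). The larger rise in PKBa-/- was called as a difference with the preset correlation (adjusted p = 3.9e-11) and not otherwise (adjusted p = 0.081 with an estimated correlation). Contractile and actin genes fell in 16 of 20 tested genes (16 adjusted over the list alone, camera adjusted p = 2.2e-06, adjusted p = 0.22 with an estimated correlation) in wild type. In PKBa-/-, 11 of 20 tested genes (11 adjusted over the list alone, camera adjusted p = 0.009, adjusted p = 0.35 with an estimated correlation) did. Chaperones of the endoplasmic reticulum rose in 11 of 19 tested genes (14 adjusted over the list alone, camera adjusted p = 8.1e-04, adjusted p = 0.37 with an estimated correlation) in wild type. In PKBa-/-, 12 of 19 tested genes (12 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.25 with an estimated correlation) did. 2700 of 7436 genes passed in wild type, 1160 up and 1540 down; 43.0% of them were up, and 52.1% after quantile normalization. In PKBa-/-, 3004 passed, 1476 up and 1528 down.

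By time 24, the epoxide hydrolase Ephx2 (3.03 ± 0.19), the lipocalin Lcn2 (2.58 ± 0.18) and the antiviral tetherin gene Bst2 (2.46 ± 0.15) had risen in wild type. In PKBa-/- Prg4 (3.36 ± 0.58), the ferritin receptor Scara5 (2.30 ± 0.12) and Vdr (2.30 ± 0.16) had risen. The smooth muscle gene Tagln fell in both (-2.77 ± 0.11 in wild type and -2.08 ± 0.11 in PKBa-/-). Contractile and actin genes fell in 19 of 20 tested genes (19 adjusted over the list alone, camera adjusted p = 4.6e-19, adjusted p = 9.2e-04 with an estimated correlation) in wild type, with Acta2 (-1.95 ± 0.10) and Tpm1 (-1.61 ± 0.13). In PKBa-/-, 14 of 20 tested genes (14 adjusted over the list alone, camera adjusted p = 1.5e-08, adjusted p = 0.084 with an estimated correlation) did. Amino acid and ATF4 response genes, which supply amino acids under stress, fell in 21 of 23 tested genes (21 adjusted over the list alone, camera adjusted p = 1.5e-17, adjusted p = 0.03 with an estimated correlation) in wild type, with Trib3 (-1.77 ± 0.12) and Chac1 (-1.50 ± 0.13). In PKBa-/- they fell in 18 of 23 tested genes (19 adjusted over the list alone, camera adjusted p = 7.5e-10, adjusted p = 0.1 with an estimated correlation). Cholesterol synthesis genes fell in wild type in 16 of 19 tested genes (16 adjusted over the list alone, camera adjusted p = 8.0e-11, adjusted p = 0.16 with an estimated correlation), with Hmgcs1 (-1.43 ± 0.20) and Idi1 (-1.27 ± 0.16). Ribosome biogenesis genes fell in wild type at time 24 in 18 of 26 tested genes (19 adjusted over the list alone, camera adjusted p = 3.6e-07, adjusted p = 0.14 with an estimated correlation) and at time 48 in 18 of 26 tested genes (19 adjusted over the list alone, camera adjusted p = 1.0e-05, adjusted p = 0.25 with an estimated correlation). Mitosis genes rose in PKBa-/- in 25 of 26 tested genes (25 adjusted over the list alone, camera adjusted p = 7.8e-22, adjusted p = 0.1 with an estimated correlation), with Ccnb2 (1.77 ± 0.14) and Cenpa (1.58 ± 0.16). 2013 of 7436 genes passed in wild type, 898 up and 1115 down; 44.6% of them were up, and 52.0% after quantile normalization. In PKBa-/-, 1969 passed, 910 up and 1059 down.

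By time 48 in wild type, Bst2 (2.86 ± 0.15), the matrix protein gene Ecm1 (2.71 ± 0.19), Lcn2 (2.43 ± 0.18) and the interferon-induced GTPase gene Gbp2b (1.93 ± 0.16) had risen. The fibroblast surface gene Thy1 (-2.20 ± 0.49), the calcium-binding S100a4 (-2.18 ± 0.21), Tagln (-2.14 ± 0.11) and the matrix glycoprotein Tnc (-1.97 ± 0.20) had fallen. In PKBa-/-, the growth factor Igf1 (2.67 ± 0.44) and its binding proteins Igfbp2 (3.30 ± 0.25) and Igfbp3 (2.21 ± 0.35), Scara5 (3.07 ± 0.12), the phosphatase Plpp3 (2.71 ± 0.25) and Prg4 (2.85 ± 0.58) had risen. Fhl1 (-2.31 ± 0.13), Slc40a1 (-2.13 ± 0.13) and Tagln (-2.01 ± 0.11) had fallen. Thy1 in wild type and Prg4 in PKBa-/- did not pass with pair averages (limma adjusted p = 0.13 and 0.087), nor did Prg4 at time 24 (adjusted p = 0.052). 2128 of 7436 genes passed in wild type, 822 up and 1306 down; 38.6% of them were up, and 51.1% after quantile normalization. In PKBa-/-, 2182 passed, 1065 up and 1117 down.

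In the averages of pairs, 886, 421 and 447 genes passed at times 6, 24 and 48 in wild type, and 1366, 457 and 554 in PKBa-/-. Replicates 1 and 2 alone gave 3924, 3317 and 3422 in wild type and 3798, 3383 and 3054 in PKBa-/-. Replicates 3 and 4 alone gave 2429, 2141 and 2432 in wild type and 2834, 2042 and 2105 in PKBa-/-. A covariate for the replicate number gave 3244, 2487 and 2698 in wild type and 3396, 2393 and 2653 in PKBa-/-. Residuals of arrays with the same number correlated above 0.1 in these comparisons except at time 24 in PKBa-/-. In wild type the array with the same number was the closest one for 3, 1 and 3 of 4 time 0 arrays. In PKBa-/- it was for 2, 2 and 2. The numbers are thus not shown to pair arrays beyond the replicate sets. The 3 times share the time 0 arrays of their genotype, so overlaps between times are not independent.

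Amino acid and ATF4 response genes fell by time 48 in 21 of 23 tested genes (21 adjusted over the list alone, camera adjusted p = 6.8e-17, adjusted p = 0.023 with an estimated correlation) in wild type, with the serine and asparagine synthesis genes Psat1 (-1.59 ± 0.15) and Asns (-1.46 ± 0.14). In PKBa-/- they fell in 14 of 23 tested genes (15 adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.3 with an estimated correlation). Contractile and actin genes fell in 19 of 20 tested genes (20 adjusted over the list alone, camera adjusted p = 6.3e-15, adjusted p = 0.0049 with an estimated correlation) in wild type. In PKBa-/-, 15 of 20 tested genes (15 adjusted over the list alone, camera adjusted p = 5.9e-10, adjusted p = 0.021 with an estimated correlation) did. The 3' minus 5' log2 signal of control probe sets, a measure of RNA quality, also moved with time, mainly in replicates 1 and 2. There the actin value went from 0.306 to 0.575 and the Gapdh value from -0.238 to 0.0161 between times 0 and 48 in wild type, with a median change of the contractile list of -0.56. Within replicates 3 and 4 they went from 0.285 to 0.303 and from -0.329 to -0.184, and the list by -0.75. In PKBa-/- actin went from 0.447 to 0.571 and Gapdh from -0.17 to -0.0434 in replicates 1 and 2 (list median -0.61). In replicates 3 and 4 they went from 0.356 to 0.403 and from -0.322 to -0.309 (list median -0.58). FoxO targets, genes restrained by insulin and PKB signalling, rose in wild type in 11 of 19 tested genes (11 adjusted over the list alone, camera adjusted p = 5.5e-05, adjusted p = 0.023 with an estimated correlation), with Sesn1 (1.67 ± 0.12) and Ulk1 (0.82 ± 0.10). Cholesterol synthesis genes fell in wild type in 16 of 19 tested genes (17 adjusted over the list alone, camera adjusted p = 3.6e-14, adjusted p = 0.1 with an estimated correlation). In PKBa-/-, 13 of 19 tested genes (14 adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.32 with an estimated correlation) did. In PKBa-/-, DNA replication genes rose in 22 of 26 tested genes (24 adjusted over the list alone, camera adjusted p = 5.9e-10, adjusted p = 0.3 with an estimated correlation), with Rrm2 (1.09 ± 0.14) and Pcna (1.02 ± 0.12). Interferon response genes fell in PKBa-/- in 5 of 10 tested genes (7 adjusted over the list alone, camera adjusted p = 4.1e-04, adjusted p = 0.011 with an estimated correlation), with Bst2 (-0.93 ± 0.15) and Psmb8 (-0.85 ± 0.08). Another 19 interferon response genes lay below the signal limit and were not tested, although their highest group mean was 389. Early adipogenic regulators rose in PKBa-/- in 6 of 12 tested genes (7 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.3 with an estimated correlation), with Cebpb (1.38 ± 0.17). Of the adipocyte genes, 10 were tested and 14 lay below the signal limit in the mean of the 36 arrays. The list was not called at time 48 in wild type or PKBa-/- (adjusted p = 0.46 and 0.94).

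**Figure D3:**
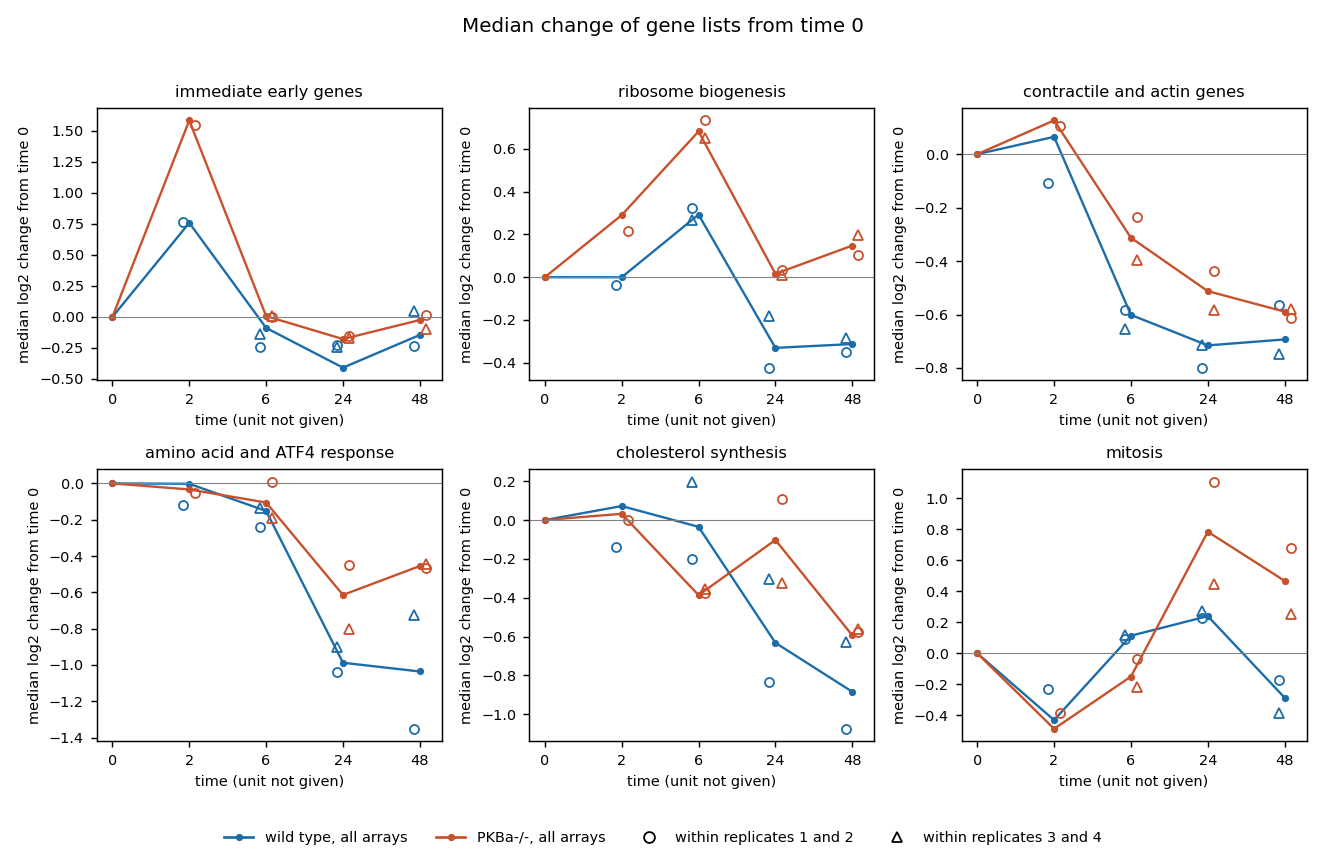
Median log2 change from time 0 of 6 gene lists, by time, in wild type and PKBa-/- arrays; lines use all arrays, circles replicates 1 and 2, and triangles replicates 3 and 4. The contractile and actin list reached -0.69 in wild type and -0.59 in PKBa-/- at time 48, while the mitosis list stood at -0.29 and 0.47.

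The interaction test asked which genes changed over time differently in the genotypes. Bst2 rose in wild type by 2.86 ± 0.15 and fell in PKBa-/- (log2 change -0.93 ± 0.15) by time 48, a difference of -3.79 ± 0.21 (adjusted p = 3.3e-14). Gbp2b differed in the same direction, by -3.09 ± 0.22, as did the muscle-type LIM protein gene Fhl1, by -2.61 ± 0.19. The interferon-induced membrane protein gene Ifitm1 (2.25 ± 0.16), the ubiquitin ligase adaptor Klhl13 (2.42 ± 0.18) and Dpt (2.21 ± 0.14) changed the opposite way. The matrix protease Adamts1 rose by 2.06 ± 0.11 by time 6 in wild type and fell in PKBa-/- (log2 change -2.15 ± 0.11). The list of interferon response genes fell in PKBa-/- relative to wild type at time 48 in 4 of 10 tested genes (4 adjusted over the list alone, camera adjusted p = 6.0e-07, adjusted p = 2.1e-04 with an estimated correlation). Mitosis genes changed upward in PKBa-/- relative to wild type by time 48 in 24 of 26 tested genes (26 adjusted over the list alone, camera adjusted p = 2.0e-15, adjusted p = 0.18 with an estimated correlation). DNA replication genes did in 18 of 26 tested genes (22 adjusted over the list alone, camera adjusted p = 3.9e-14, adjusted p = 0.13 with an estimated correlation). FoxO targets changed downward in 8 of 19 tested genes (9 adjusted over the list alone, camera adjusted p = 1.9e-04, adjusted p = 0.064 with an estimated correlation). In the F test over the 4 times, 1614 of 7436 genes passed, and 130 with pair averages. The test gave 3952 within replicates 1 and 2 and 2220 within replicates 3 and 4. In simulated data without any change, in which the arrays of a pair shared a deviation, 1120 genes passed this test and 0 with pair averages. Those deviations were drawn anew for each group. In the data the difference between replicate sets correlated over times (mean r = 0.677 in wild type and 0.604 in PKBa-/-). The 1120 therefore does not carry over as such, and how many of the 1614 genes differ is not settled. The 12 genes chosen by the naming rule, which include those above, passed with pair averages too.

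**Figure D4:**
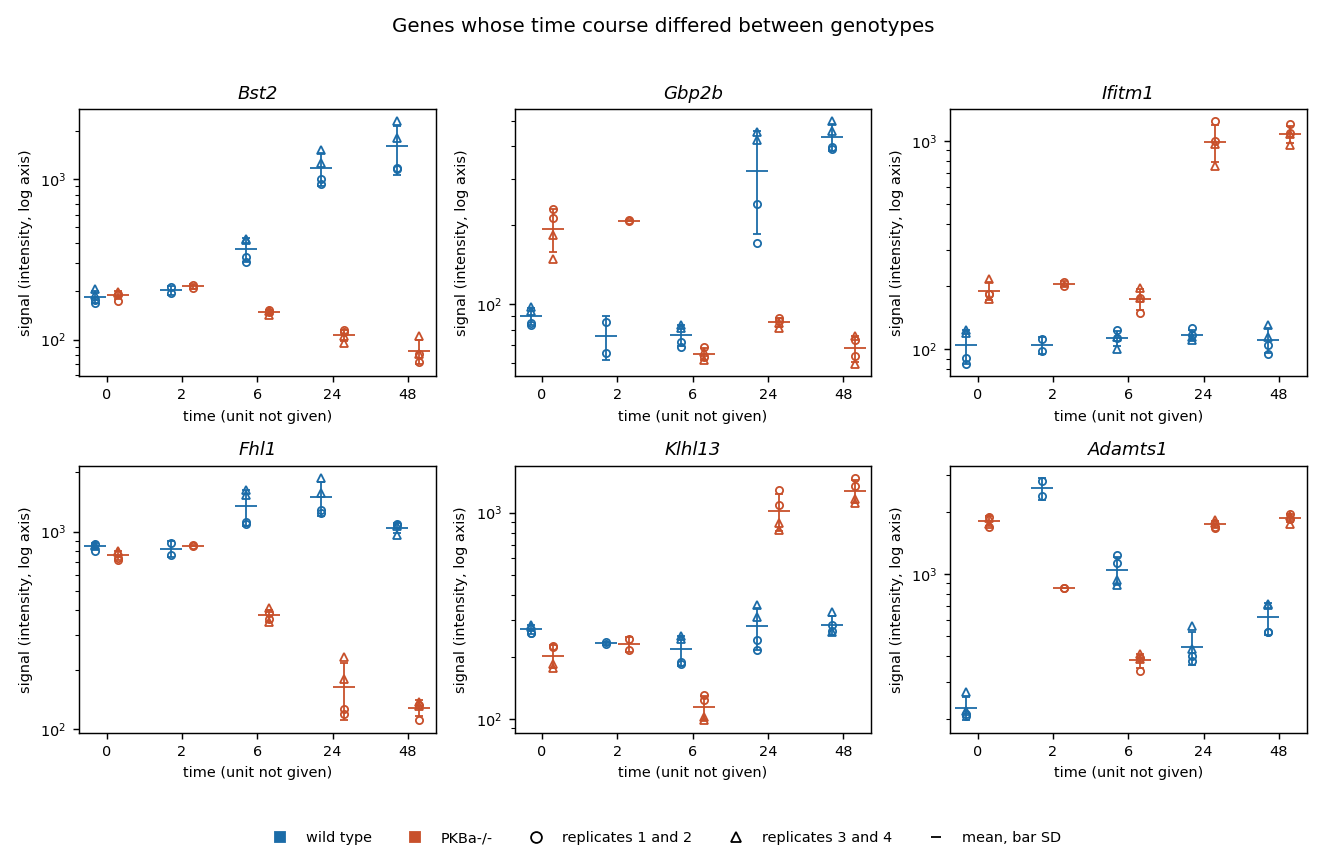
Signal on a log axis of 6 genes from the interaction test, for each array by time and genotype, with group means and SD. At time 48, Bst2 read 1604 ± 542 in wild type and 84.8 ± 14.0 in PKBa-/- (n = 4 each), and Ifitm1 111 ± 15.2 and 1079 ± 102.

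Across the 7436 tested genes, the changes from time 0 in wild type and PKBa-/- were compared as a description, since genes are not independent replicates. Pearson's r was 0.627, 0.669, 0.515 and 0.426 at times 2, 6, 24 and 48, and Spearman's rho 0.491, 0.664, 0.508 and 0.401. Within replicates 1 and 2, r was 0.667, 0.638, 0.47 and 0.456, and within replicates 3 and 4 it was 0.629, 0.492 and 0.325 from time 6 on. At time 6, 1778 genes passed in both genotypes in any direction, against 1091 if passing were independent, and 1713 of the 1778 changed in the same direction. At time 48, 996 passed in both, against 624, and 879 of the 996 changed in the same direction. The tests of both genotypes share 1 estimate of the spread per gene, so an overlap above independence is partly built in.

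Markers of other cell types were mostly below the signal limit: 24 skeletal muscle, 17 macrophage, 14 epithelial, 13 neural and 12 endothelial genes had a mean too low to be tested. Over the genotype contrast averaged over times and the 8 time contrasts, 68 of 288 list tests passed with the preset correlation and 15 with an estimated one.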

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

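The tests of explanations in this part, with their bounds, were chosen after the results were seen. The added marker and target genes on which no pattern was noticed were listed before their values in the contrasts tested were seen. Exceptions are Nfil3 and Pfkfb3, which had already been named for a change at time 2. The interaction and single-array checks were planned.

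Genes typical of mesothelium were lower in PKBa-/-, with a median of -4.13 over the 9 on which the pattern was noticed (Upk3b 4543 against 60.9, Wt1 1001 against 42.0 in mean signal, wild type first), while Hoxc8, Tnmd, Dpt and Zic1 were higher. A minor share of other cells in the wild type cultures, if otherwise alike, lowers a gene there at most 2-fold. Yet 110 genes were more than 2-fold higher in PKBa-/- by over 2 SE (104 with pair averages), which argues against such a share as the whole cause. Other cells in the PKBa-/- cultures are not covered by this bound and were not tested. Mesothelial-type cells in the wild type cultures may contribute: of 18 further markers 6 were tested and 5 were lower, with a median of -0.95 (camera p = 7.8e-05, and p = 0.0037 with an estimated correlation). Among listed genes below the filter, Krt8 (116 against 115), Krt18 (29.8 against 29.1) and Hand2 (20.8 against 22.5) were alike, while Krt7 (123 against 34.0), Krt19 (116 against 68.7), Msln (240.1 against 42.2) and Tcf21 had higher means in wild type, so this stays open. Separate origin of the cultures and loss of PKBa cannot be told apart, since 22 of 24 tested positional genes differed (17 with pair averages) and the labels name no independent lines of either genotype. Of all 7436 tested genes, 4845 differed (3521 with pair averages).

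Glucocorticoid and cAMP target genes were higher after time 0 in both genotypes, and a passing response to fresh medium and serum would be over by time 48, which the glucocorticoid targets argue against: over 12 targets on which the pattern was not noticed, the median was still 0.41 in wild type and 0.55 in PKBa-/-. For the cAMP targets it stays open, since the median over 11 of them was back at 0.11 and 0.064. Glucocorticoid in the medium is a candidate explanation: these 12 targets ranked high in 4 of 4 tests, with medians of 0.31 and 0.39 at time 24 in wild type and PKBa-/- (highest camera adjusted p = 2.3e-04, and 0.0019 with an estimated correlation). Raised cAMP, which may also pass, is another: these 11 targets ranked high in 4 of 4 tests, with medians of 0.44 and 0.67 at time 2 within replicates 1 and 2 and 0.49 and 0.34 at time 6 (highest camera adjusted p = 0.0059, and 0.022 with an estimated correlation). Nfil3 and Pfkfb3 among the 11 had already been named for a change at time 2. The time 2 tests thus do not rest on unseen genes alone. Without untreated arrays at the later times, time in culture and cell density stay open, and the sample labels do not say which medium was used.

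Mitosis and DNA replication genes changed upward by time 48 in PKBa-/- relative to wild type, with a median interaction of 0.71 over 52 genes. The 2 replicate sets (1 and 2, 3 and 4) do not account for it, since the median was 0.78 within replicates 1 and 2 and 0.65 within replicates 3 and 4. A lower starting level in PKBa-/- alone is argued against as well: the genotypes differed by -0.18 and -0.37 at time 0, but at time 48 by 0.57 and 0.32 in the other direction. Loss of PKBa and other differences between the cultures cannot be told apart, as 400 genes differed at least 2-fold between the genotypes already at time 0.

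In 1614 genes the test for a different time course between the genotypes passed, with the limit of shared deviations given above. Among genes named for a change over time, the change in PKBa-/- minus that in wild type passed at time 2 for Ahr (2.34), Ccl2 (2.78), Cxcl1 (2.29), Errfi1 (1.19), Id1 (2.64), Ramp3 (-3.42) and Rgs2 (-1.80). At time 6 it passed for Adamts1 (-4.21), Adamts5 (-1.74), Ccl2 (2.42), Has2 (1.72), Nolc1 (0.86), Pdgfrb (1.33), Ramp3 (-3.36), Rgs2 (-1.96), Slc40a1 (-2.26) and Vdr (2.62). By time 24 the genes were Acta2 (1.06), Bst2 (-3.14), Ccnb2 (1.03), Cenpa (1.16), Ephx2 (-3.07), Hmgcs1 (1.28), Idi1 (1.54), Lcn2 (-2.28), Scara5 (1.40), Tagln (0.68), Tpm1 (0.65) and Vdr (2.03). By time 48 they were Asns (0.77), Bst2 (-3.79), Cebpb (0.72), Ecm1 (-2.37), Fhl1 (-2.61), Gbp2b (-3.09), Igfbp2 (4.15), Igfbp3 (1.61), Lcn2 (-2.13), Pcna (1.01), Plpp3 (2.59), Psat1 (1.18), Psmb8 (-0.93), Rrm2 (1.01), S100a4 (2.13), Scara5 (1.67), Sesn1 (-0.77), Slc40a1 (-2.17), Tnc (1.02) and Ulk1 (-0.69). These calls count arrays as replicates. Over all genes they numbered 164, 655, 613 and 1064 at times 2, 6, 24 and 48, and 18, 41, 54 and 85 with pair averages. Of the genes named here, those that passed with pair averages were Id1 at time 2, Adamts1, Adamts5, Ramp3, Slc40a1 and Vdr at time 6, Bst2, Ephx2, Lcn2, Scara5 and Vdr at time 24 and Bst2, Ecm1, Fhl1, Gbp2b, Igfbp2, Lcn2, Psmb8, S100a4, Scara5 and Slc40a1 at time 48. At time 2 the values compare replicates 1 and 2 with time 0 arrays of both replicate sets; within replicates 1 and 2 they were Ahr 1.94, Ccl2 2.38, Cxcl1 1.63, Errfi1 1.56, Id1 2.49, Ramp3 -3.34 and Rgs2 -1.89.

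For the lists named above, the interaction was called by camera with the preset correlation at time 2 for these, with the median over their genes: FoxO targets (-0.066), NF-kB and cytokines (0.32), TGF-beta targets (0.38), adipocyte (-0.20), cholesterol synthesis (-0.10), immediate early genes (0.31) and ribosome biogenesis (0.27). At time 6 they were DNA replication (0.21), FoxO targets (-0.21), TGF-beta targets (0.63), cholesterol synthesis (-0.35), contractile and actin genes (0.19), interferon response (-0.29), mitosis (-0.23) and ribosome biogenesis (0.37). At time 24 they were amino acid and ATF4 response (0.23), cholesterol synthesis (0.75), contractile and actin genes (0.36), interferon response (-0.24), mitosis (0.55) and ribosome biogenesis (0.34). At time 48 they were DNA replication (0.70), FoxO targets (-0.40), amino acid and ATF4 response (0.39), cholesterol synthesis (0.33), interferon response (-0.24), mitosis (0.73) and ribosome biogenesis (0.40). With an estimated correlation over the 36 arrays the calls that held were TGF-beta targets at time 2, adipocyte at time 2, immediate early genes at time 2 and interferon response at times 6, 24 and 48. At time 2 these interactions compare replicates 1 and 2 with time 0 arrays of both replicate sets. Within replicates 1 and 2 the call for cholesterol synthesis ended and its sign turned (median 0.12, adjusted p = 0.73). The median of NF-kB and cytokines went to -0.015 there (adjusted p = 0.013, and 0.078 with an estimated correlation). With an estimated correlation within replicates 1 and 2, the adipocyte call was lost (adjusted p = 0.078), and those for TGF-beta targets and immediate early genes held (adjusted p = 0.0057 and 0.0018).

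Single arrays stood apart from the other 3 of their group, relative to the range of the 4, in 18 of 482 groups of values. About 1 in 20 is the share by chance for 4 independent values, which arrays in pairs are not. Where the range is small, such an array can lie close to the others in value. The 3' minus 5' signal of actin was 0.262 on wild type time 0 replicate 4. In signal the genes and arrays were Adamts5 on PKBa-/- time 6 replicate 4 (146), Akt2 on PKBa-/- time 6 replicate 1 (567), Cebpb on PKBa-/- time 0 replicate 2 (1479), Chac1 on wild type time 0 replicate 4 (566), Chac1 on wild type time 24 replicate 4 (166), Col7a1 on wild type time 48 replicate 4 (273), Col7a1 on PKBa-/- time 48 replicate 3 (537), Dpt on PKBa-/- time 24 replicate 4 (1907), Dpt on PKBa-/- time 48 replicate 3 (4496), Ephx2 on wild type time 24 replicate 2 (865), Fhl1 on wild type time 48 replicate 4 (960.2), Fos on PKBa-/- time 0 replicate 4 (154), Gpm6a on wild type time 48 replicate 4 (747), Gsta4 on wild type time 48 replicate 4 (898), Hoxb2 on wild type time 6 replicate 2 (377), Prg4 on PKBa-/- time 0 replicate 1 (46.5) and Xist on wild type time 0 replicate 3 (6064).

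Outside the genes compared, 499 probe sets without a listed gene passed between the genotypes averaged over times, 41 of them at least 2-fold apart.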

How the results depend on the processing

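Pair averages, a random pair, the replicate set block within each genotype and the replicate block for the lists were chosen after seeing the data; the other settings were planned. Of 9632 recomputations of the 363 results for named genes, 9416 stayed on the same side of the threshold. Results that had passed did so again in the same direction. Results that had not passed, such as Akt2, were judged by the threshold alone, whatever their sign. In the other recomputations a result that had passed kept its direction and no longer passed. Most of the others came from pair averages (93), leaving out 1 array (67) and the random pair (31), which count fewer units. Of the 9416, 3981 left out a single array. Apart from Akt1, Akt2 and sex-linked genes, the named genes were chosen from the same data for large changes, small p-values or list calls. That choice favours staying past the threshold, so the 9416 say little about genes not named. Akt1 ran from -3.48 to -3.43 without single arrays. The gene counts stayed within 1.5-fold with an offset of 1 or 100, no filter or a 60% filter, the mean of all probe sets, quantile normalization, the intensity trend and the replicate block.

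Pair averages gave 1102, 430, 1229, 1520 and 1726 genes between genotypes at times 0, 2, 6, 24 and 48, 203, 886, 421 and 447 for times 2, 6, 24 and 48 in wild type, 252, 1366, 457 and 554 in PKBa-/-, and 130 for the interaction. Treating the 2 arrays of a pair as a random block gave, in the same order, 1472, 667, 1553, 1867 and 2119, then 411, 1265, 671 and 753, then 393, 1671, 747 and 912, and 501. Both lower the number of independent units, as their construction implies. Array weights gave 3591 genes between genotypes at time 2, 2347, 4239, 3738 and 3386 in wild type, 2642 and 3258 at times 2 and 24 in PKBa-/-, and 3998 for the interaction; the cause was not tested. A replicate set block gave 2583 for the interaction. Set within each genotype, it gave 3113 there, 2707 between genotypes at time 2, and 3144 and 3281 at times 24 and 48 in wild type. Both remove the difference between replicate sets from the spread.

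Replicates 1 and 2 only gave 3664 genes between genotypes at time 2, 2416, 3317 and 3422 at times 2, 24 and 48 in wild type, 2003 and 3383 at times 2 and 24 in PKBa-/-, and 3952 for the interaction. Replicates 3 and 4 hold no time 2, so their average over times covers 4 times. With only the groups compared in the fit, 3639 genes passed between genotypes at time 2. There, as with replicates 1 and 2 only, the spread is that within pairs alone. At time 48 in wild type 1286 passed, and the cause of that count was not tested.

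Without single arrays, the counts ran over 4603 to 4947 for genotype averaged over times, 2625 to 2981, 1016 to 1244, 2597 to 2804, 2859 to 3083 and 3219 to 3362 at times 0, 2, 6, 24 and 48, 629 to 1312, 2360 to 2588, 1601 to 1832 and 1724 to 2093 for the changes in wild type, 565 to 1096, 2665 to 2846, 1626 to 1954 and 1814 to 1990 in PKBa-/-, and 1403 to 1734 for the interaction. The comparisons with time 2 fell most, down to 1016 without wild type time 2 replicate 1 between genotypes, 629 without it in wild type and 565 without PKBa-/- time 2 replicate 2. A group left with 1 array was assumed to vary like the others.

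Of the list tests, 68 passed with the preset correlation, 15 with an estimated correlation, 160 with fry, which does not compare a list with other genes, and 75 with a replicate block (4 lost, 11 gained). The correlation between the genotypes' changes moved from 0.627 to 0.73 over genes passing in either genotype and 0.667 within replicates 1 and 2 at time 2. At time 6 it moved from 0.669 to 0.698, 0.638 and, within replicates 3 and 4, 0.629. At time 24 it moved from 0.515 to 0.557, 0.47 and 0.492, and at time 48 from 0.426 to 0.325 within replicates 3 and 4. The filter limits the lists, since listed genes below it were not tested. It left out a share of genes set beforehand, so the 4957 of 12393 genes below it do not measure signal over background.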

Other observations

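The tests in this part were chosen after the results were seen.

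Replicates 1 and 2 differed from replicates 3 and 4 within a genotype; the labels do not say what set them apart, such as a round of arrays, a culture or an embryo. The 3' minus 5' log2 signal of control probe sets, a measure of RNA quality, went with the replicate set too. For Gapdh it was -0.144 against -0.28 in wild type and -0.154 against -0.299 in PKBa-/- (replicates 1 and 2 first), and for actin 0.427 against 0.332 and 0.464 against 0.327. Its part in the differences between replicate sets was not tested. Differences, replicates 3 and 4 minus replicates 1 and 2, were averaged over times 0, 6, 24 and 48. The sets differed at least 2-fold in 97 genes in wild type and in 7 genes in PKBa-/-. Many more genes passed between the sets, 4136 in wild type and 4590 in PKBa-/-, most of them less than 2-fold apart. In wild type the imprinted genes Mest (-2.69 ± 0.07), Grb10 (-2.34 ± 0.04) and Plagl1 (-2.21 ± 0.05) were lower in replicates 3 and 4, with Crabp2, which binds retinoic acid, -2.66 ± 0.06, and the chemokine Cxcl15 (2.53 ± 0.06) was higher. In PKBa-/- Igf2 (-1.86 ± 0.04), Igfbp4 (-1.58 ± 0.05) and the opioid precursor Penk (-1.21 ± 0.06) were lower. These are the genes with the largest differences, or the imprinted genes among them, and were chosen after their values were seen.

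Among the neighbours of Akt1 in the gene order of assembly GRCm38.p6, Crip1 (-3.19) and Crip2 (-1.48), which encode LIM-domain proteins, were lower in PKBa-/- averaged over times. Differences around the Akt1 locus, as DNA of another strain kept beside a targeted gene might leave, stay open. In size, the 20 nearest tested genes other than Crip1 and Crip2 had a median of 0.17, larger than 46.1% of 7026 windows of as many neighbouring genes, whose median was 0.18. With Crip1 and Crip2 kept in, the 22 genes had a median of 0.19, larger than 54.1% of 6984 such windows. In sign, 15 of 20 were lower in PKBa-/-, more than in 88.1% of windows, and 17 of 22 with Crip1 and Crip2, more than in 91.3%. Of those that passed, 10 were lower and 1, Ckb, was higher, apart from Crip1 and Crip2. A variant reaching Crip1 and Crip2 alone was not tested.

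Other splits of the arrays into groups of the same sizes were counted, which treats the arrays as exchangeable although they form pairs. With the genotypes exchanged within each time, 1 of 100 splits drawn, the real one, gave as many as 4845 genes averaged over times (highest other 17), and 1 of 100 as many as 1614 for the interaction (highest other 575). Such an exchange also mixes the average difference between the genotypes into the spread and into the changes over time. For the interaction these splits thus cannot decide. Between genotypes at times 0, 6, 24 and 48, 1 of 35 splits each, the real one, gave as many as 3072, 2937, 3169 and 3487 genes, and the highest others gave 2, 1, 875 and 825. For times 6, 24 and 48 against time 0, again 1 of 35 gave as many as 2700, 2013 and 2128 in wild type, with 1049, 1011 and 1361 as the highest others. In PKBa-/- the real counts were 3004, 1969 and 2182 and the highest others 368, 964 and 1. Chance is thereby excluded for the counts other than that of the interaction, and only as far as the arrays are exchangeable, which those of a pair are not. For the interaction, deviations shared by pairs gave 1120 genes in simulated data without any change. They were drawn anew for each group there, whereas the real differences between replicate sets correlated over times. The size of the real count is thus not settled. Pair averages, which take up such deviations, gave 130 genes here and 0 in the simulated data. The highest other split was the one between the 2 replicate sets at times 6, 24 and 48 in wild type and at time 24 in PKBa-/-. Some comparisons had residual correlations above 0.1 between all arrays of the same replicate number. There the other splits that parted the arrays of each number gave at most 1, 1 and 13 at times 6, 24 and 48 in wild type. In PKBa-/- they gave at most 0 and 0 at times 6 and 48, and between genotypes 434 and 6 at times 24 and 48. The remaining splits leave the 2 arrays of some numbers together. Between genotypes the array of the same number was the closest for 1 of 4 at time 24 and 0 of 4 at time 48. The numbers are thus not shown to be pairs.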
